A study of Homo sapiens with 6 samples.

How the data were processed

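RNA from HCT116 cells, an established human colorectal cancer line, was profiled by RNA sequencing in 6 libraries, with 3 from cells given a vector and 3 from cells given a plasmid that overexpresses MST3 (gene symbol STK24). Per the labels' protocols, plasmids were introduced by lipofection at 60% density, the medium was renewed after 6 hours and RNA was taken after 30 hours by phenol and chloroform extraction. The labels number the libraries 1 to 3 in each group and do not say whether the numbers mark separate cultures, so each p-value measures only the spread between these samples, which may be technical.

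The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled by a factor for each library) with 1 column per library and with the position, length and biotype of each gene. HISAT2 is named as a tool per the submitters' processing notes. Its version, the counting program, the strand setting, the genome build and the annotation release are not given in the sources used here. The table holds 58938 entries, of which 58735 carry Ensembl identifiers. All 58735 have the same chromosome, start, end and strand in GENCODE 29 on GRCh38, so coordinates are given on that build. The other 203 entries are loci without an Ensembl identifier, and 98 of them were expressed highly enough to be tested.

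An FPKM value multiplied by gene length was a whole multiple of a single step in 100.0% of values in each library, within a tolerance of 0.01, which gives the number of reads behind each value. The recovered reads came to 17708029, 17506541 and 17296201 for vector replicates 1 to 3, and to 15289213, 17209736 and 17178700 for MST3 replicates 1 to 3. On a gene of 1 kb, 1 read was worth 0.0569 to 0.0583 FPKM in the vector libraries and 0.0576 to 0.0627 FPKM in the MST3 libraries. The denominators implied by the steps were 15950197 to 17576830 reads, and gene totals divided by them ranged from 0.959 to 1.021. Since the gene total exceeded the denominator in some libraries, the scaling was not by the read total alone.

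Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), over the 13036 genes with a mean of at least 1 FPKM across the 6 libraries. The Benjamini-Hochberg adjustment was applied over all of these genes with a threshold of 0.05. All tests were two-sided. A fold change on this scale understates the change of genes with low values, so ratios of mean FPKM are given beside it. For STK24 and YAP1 an exact permutation test of the 6 values was added, for which 3 libraries against 3 allow no p below 0.1.

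Gene lists were compared with all other tested genes by camera in limma, with a preset inter-gene correlation of 0.01 and adjustment over lists. Camera was repeated with a correlation estimated for each list, and fry, a rotation test of whether the members of a list move on balance in 1 direction, was run beside it. Of 26 lists, 22 had at least 5 tested members, and the other 4 are given as levels. The replicate numbers were not used as pairs. The groups, the tests, the lists, the naming rule and all alternatives not described as added later were fixed before the data were examined. Genes were named by rule. STK24 came first, followed by up to 12 protein-coding genes per direction with an adjusted p under 0.05 and groups that do not overlap, with no others added where fewer passed. The rule also took up to 4 members with the smallest p from each tested list, and a panel of 14 genes in any case (YAP1, WWTR1, PGAM5, STK25, STK26, PDCD10, CCN1, CCN2, ANKRD1, AMOTL2, AXIN2, MYC, CCND1 and CDKN1A). FARP1, RN7SL2 and 1 unannotated locus fall outside the rule and were chosen after their values were seen.

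Alternatives covered the pseudocount (0.1 and 0.01), the expression filter (mean FPKM of 0.1, 5 or none), the scaling of libraries (equal sums with and without STK24, median-of-ratios factors, quantile normalization), the variance model (no trend, robust, sample weights), the replicate number as a block, and each library left out in turn. Added after seeing the data were limma voom on the recovered reads, removal of each library's trend with gene length and GC content by natural splines with 3 degrees of freedom, protein-coding genes alone, and a fit without MST3 replicates 1 and 3. GC content was taken from the longest GENCODE 29 transcript of each gene, and 99.2% of the tested genes had a GC value. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

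The fit was tested on simulated data for the comparison of MST3 overexpression with vector, with 13036 genes of which 200 were changed. It recovered 12.7% of genes changed 1.5-fold, 67.6% of those changed 2-fold and 87% of those changed 4-fold, and 7.3% of its calls were false. On the same data voom recovered 61.9, 88.2 and 94.2% of them, with 2.4% false calls. The simulation gave every library the same spread and no trend of its own. In the real libraries the median SD of log2 values was 0.09 for vector and 0.16 for MST3, so these rates may not hold for them. With no change simulated, 0 genes and 0 lists were called. Each gene was simulated independently, so this does not show how often a list is called falsely when its genes vary together. In the real libraries the estimated correlation was 0.38 for ribosomal proteins, 0.36 for G2/M, 0.18 for Hippo and 0.09 for oxidative phosphorylation genes.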

Results

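HCT116 is an established human colorectal cancer cell line. Its mRNA was measured by RNA sequencing in 3 libraries from cells transfected with a vector and 3 libraries from cells transfected with a plasmid for MST3, a protein kinase of the GCKIII family encoded by STK24. The RNA was collected 30 hours after transfection. Values were FPKM as the authors scaled them, and the reads recovered from them came to 17296201 to 17708029 per vector library and 15289213 to 17209736 per MST3 library. Reads were found on 25099 to 25501 genes per vector library, and on 27442, 25378 and 25125 genes in MST3 replicates 1 to 3. Mitochondrially encoded mRNAs made up 5.54, 4.68 and 3.6% of the signal in the vector libraries and 4.71, 3.77 and 3.25% in the MST3 libraries. Pearson's r across genes (which are not independent replicates) was 0.9812 to 0.9844 between vector libraries and 0.9662 to 0.9701 between MST3 libraries.

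The comparison of MST3 overexpression with vector asks what the kinase does to gene expression in colon cancer cells, and the series title ties MST3 to the mitochondrial phosphatase PGAM5 and to activation of YAP. The FPKM of STK24 rose about 4-fold, and STK24 was the only gene to pass the test over all genes. YAP1 mRNA was lower in all 3 MST3 libraries than in any vector library, but it did not pass over all genes. The differences of CCN1, CCN2 and AMOTL2, the tested YAP target genes of the fixed panel, and of PGAM5, had 95% intervals that include 0. The libraries measured mRNA alone, so the proteins and the activation of YAP that the title names were not measured. As lists, mRNAs for ribosomal proteins and for nuclear-encoded oxidative phosphorylation ranked higher than other genes, and those of the Hippo pathway and of G2/M ranked lower, by small amounts that did not pass without MST3 replicate 1. With an estimated correlation none of the 4 passed (adjusted p = 0.843 for each), and fry called 0 lists (smallest unadjusted p = 0.118).

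STK24 (ENSG00000102572; chromosome 13, 98445185 to 98577940, minus strand, GRCh38) rose from 17.3 ± 0.161 to 70.7 ± 6.3 FPKM (SD, n = 3 per group), a ratio of 4.08. Its values were 17.1, 17.4 and 17.4 FPKM in the vector libraries and 63.7, 72.2 and 76 FPKM in the MST3 libraries. On the log2 scale the difference was 1.97 (SE 0.09, 95% interval 1.75 to 2.18), with an adjusted p = 0.000998 over all genes. An exact permutation test of the 6 values gave p = 0.1, the smallest that 3 libraries against 3 allow. The mean reads behind the values were 3634 per vector library and 14389 per MST3 library. They were summed over the whole gene, so reads of the plasmid and of the chromosomal gene were not separated. All were divided by a single gene length of 12077 bp. The ratio need not equal that of mRNA copies if the plasmid transcript has another length. FARP1, chosen after its values were seen because it overlaps the end of STK24 on the opposite strand, stood at 2.97 ± 0.135 FPKM in vector and 2.42 ± 0.178 in MST3 libraries (SD, n = 3; adjusted p = 0.719).

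Of the 13036 genes tested by limma, 1 was higher (STK24) and 0 were lower. In the simulation this fit recovered 12.7% of genes changed 1.5-fold, so changes of that size can be missed. At an unadjusted p under 0.05 there were 458 higher and 243 lower, 701 in all, where chance gives 652. This count depended on single libraries, with 444 without vector replicate 1, 298 without vector replicate 2, 452 without MST3 replicate 1 and 2554 without MST3 replicate 2, and it was 1338 with the replicate number as a block. Limma voom on the recovered reads also called 1 gene, with 871 at an unadjusted p under 0.05. The second smallest adjusted p was 0.429. The groups did not overlap for 1550 genes, or 11.9%, where chance gives 10%. The 95% interval lay within 1 of 0 on the log2(FPKM + 1) scale for 12283 genes (94.2%), a looser bound on the ratio of genes with low FPKM than of others. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

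**Figure D1:**
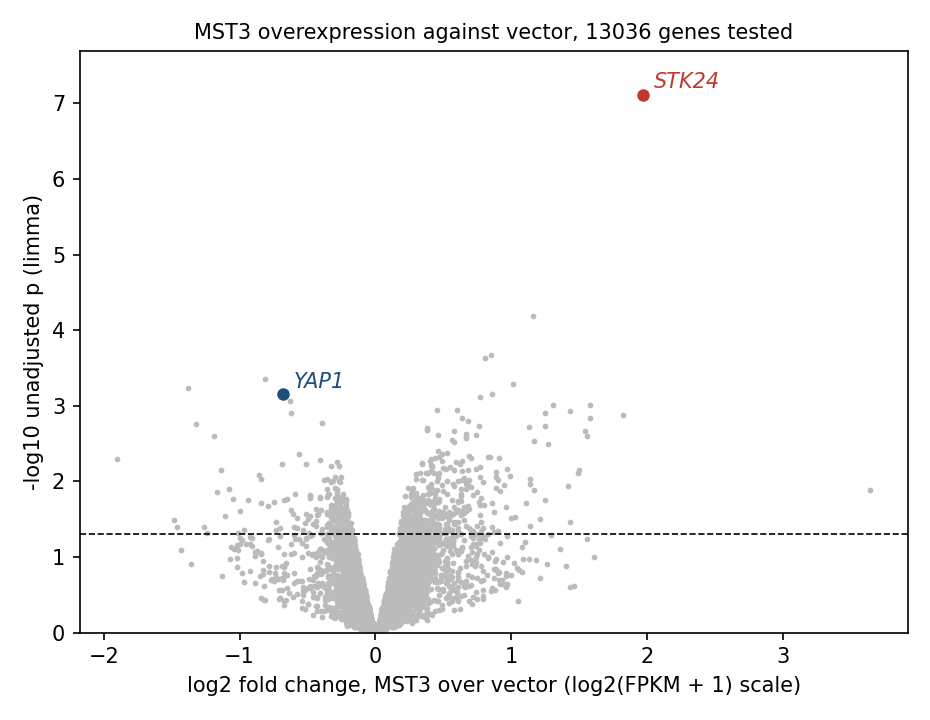
Each point is 1 of the 13036 genes tested, with the log2 fold change of MST3 overexpression over vector on the horizontal axis and the unadjusted limma p (as -log10) on the vertical axis. STK24 stands apart at 1.97, and YAP1 lies at -0.68.

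YAP1 (ENSG00000137693; chromosome 11, 102110461 to 102233423, plus strand) stood at 203 ± 4.39 FPKM in vector and 127 ± 18.5 FPKM in MST3 libraries (SD, n = 3), a ratio of 0.626. The vector libraries had 197, 205 and 205 FPKM and the MST3 libraries 107, 129 and 144 FPKM, from a mean of 22172 and 13476 reads. The log2 difference was -0.68 (SE 0.12, 95% interval -0.97 to -0.40). The unadjusted p by limma was 0.000695, where 9.06 genes with so small a p are given by chance. Under the alternatives that p ranged from 6.79e-05 (limma voom) to 0.00395 (without vector replicate 3), so the chance count depends on the fit. Its adjusted p = 0.719 over all genes. Adjusted over the list alone it was 0.0278 among Hippo pathway components and 0.00903 among the 13 tested genes of the panel of 14, where it was the only panel gene under 0.05. The exact permutation p = 0.1, again the smallest possible.

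PGAM5 had 22.2 ± 1.46 FPKM in vector and 26.3 ± 4.72 in MST3 libraries (SD, n = 3), a log2 difference of 0.22 with a 95% interval of -0.10 to 0.53. The interval for CCN1 was -0.33 to 0.27 (10 ± 1.48 against 9.78 ± 1.25 FPKM), for CCN2 -0.45 to 0.10 (2.52 ± 0.122 against 2.13 ± 0.42) and for AMOTL2 -0.20 to 0.20 (6.51 ± 0.34 against 6.52 ± 0.565). ANKRD1, another YAP target, averaged 0.0446 FPKM over the 6 libraries and was too low to test. WWTR1, which encodes TAZ, had 15.2 ± 1 and 14 ± 1.01 FPKM, with an interval of -0.32 to 0.10. The kinases closest to MST3 stood at 12 and 13.6 FPKM for STK25 (log2 difference 0.15) and at 12.6 and 11.5 FPKM for STK26 (-0.13), and their partner PDCD10 at 12.9 and 12.6 FPKM (-0.04). The log2 differences of the other panel genes were 0.18 for AXIN2, -0.16 for MYC, -0.08 for CCND1 and 0.15 for CDKN1A. No panel gene but YAP1 had an unadjusted p under 0.05 by limma, and CDKN1A and PGAM5 both had an adjusted p = 0.719 over all genes.

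**Figure D2:**
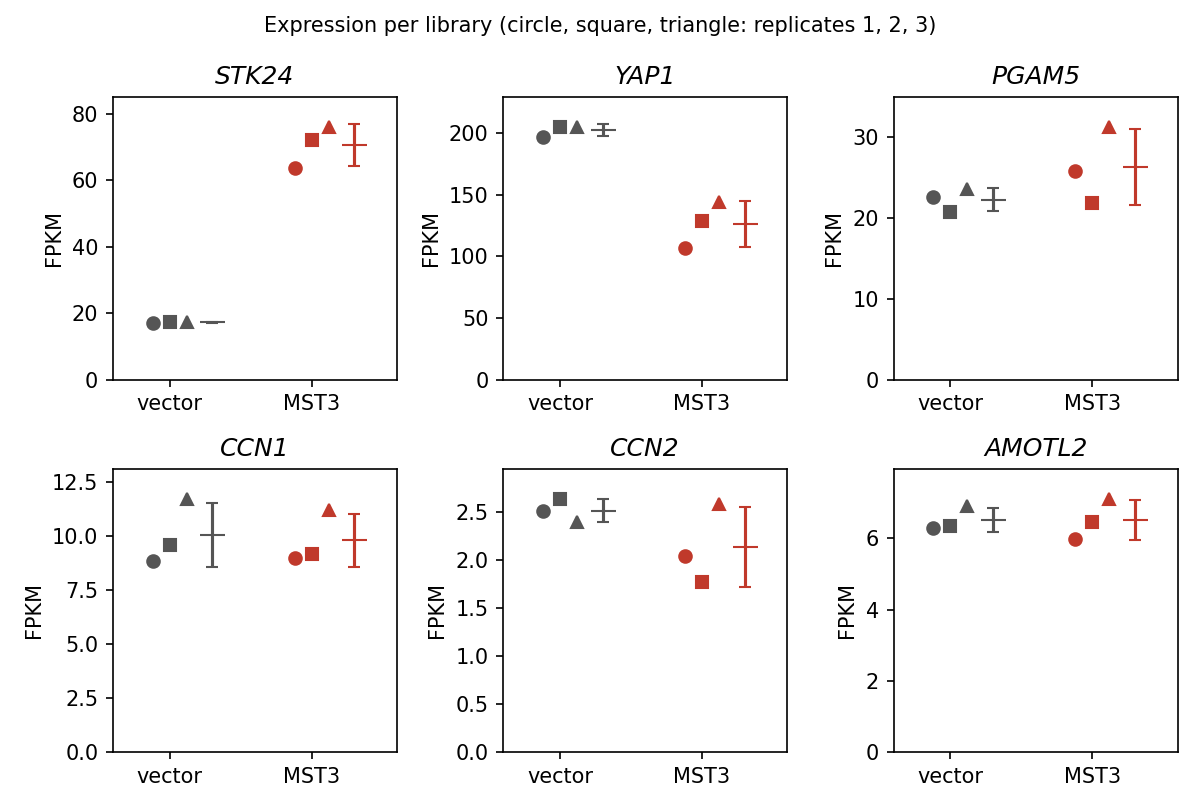
FPKM of STK24, YAP1, PGAM5, CCN1, CCN2 and AMOTL2 in each library, with points for libraries and bars for the mean ± SD of 3 libraries per group. The MST3 libraries lie at 63.7 to 76 FPKM for STK24 and at 107 to 144 FPKM for YAP1, and the groups overlap for PGAM5, CCN1, CCN2 and AMOTL2.

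Among Hippo pathway components, 30 of 40 tested mRNAs were lower in the MST3 libraries, with a mean log2 difference of -0.08 and a median of -0.09. Camera ranked the list below other genes (adjusted p = 0.038 with the preset correlation), and adjusted p = 0.843 with an estimated correlation. Its median was -0.14, -0.02 and -0.10 in MST3 replicates 1 to 3, and its mean was -0.03 without MST3 replicate 1 (adjusted p = 0.402). None of the list passed limma over all genes, and 1, YAP1, passed when adjusted over the list alone. The list was not tested without YAP1, so its call and the YAP1 value are not separate results. AMOT had 4.54 FPKM in vector and 3.63 in MST3 libraries, while VGLL4 (4.68 and 5.56) and TEAD2 (7.93 and 9.47) lay the other way. The YAP/TAZ target genes had 16 of 24 tested members lower, with a mean of -0.07, a median of -0.10 and an adjusted p = 0.131 by camera. The mean of these targets was -0.02 without MST3 replicate 1, and -0.10 without MST3 replicate 3, where the list passed with the preset correlation (adjusted p = 0.0288). With all 6 libraries and an estimated correlation the adjusted p = 0.843 for these targets. IGFBP3 on that list had 3.87 ± 0.491 and 2.88 ± 0.398 FPKM (SD, n = 3; adjusted p = 0.719) and MYOF 52.1 and 44.5 FPKM. Among STRIPAK and GCKIII genes, 17 of 24 were lower, with a median of -0.04 and a test direction of down (adjusted p = 0.679 by camera over all 24), but STK24 gave the mean the other sign, 0.04. Without STK24 the mean was -0.04, which was not tested. A rotation test for change in either direction gave that list an adjusted p = 8.67e-05, with STK24 among its members. PPP2CA, a phosphatase subunit of the complex, had 25.2 and 21.2 FPKM.

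Cytosolic ribosomal protein mRNAs were higher for 30 of 40 genes, with a mean log2 difference of 0.14 and a median of 0.08. Camera ranked them above other genes (adjusted p = 0.0164 with the preset correlation), and adjusted p = 0.843 with an estimated correlation. RPLP2 had 224 ± 6.59 and 316 ± 85.5 FPKM, RPL8 718 ± 73.5 and 989 ± 243, and RPS2 1070 ± 147 and 1460 ± 333 (SD, n = 3; adjusted p = 0.719 for each), from genes with many pseudogene copies that can share reads. The median of the list was 0.24 in MST3 replicate 1, -0.01 in replicate 2 and 0.02 in replicate 3, against -0.02 to 0.03 in the vector libraries. Nuclear-encoded oxidative phosphorylation mRNAs were higher for 26 of 42 genes, with a mean of 0.13, a median of 0.05 and an adjusted p = 0.038 by camera. With an estimated correlation the adjusted p = 0.843. NDUFA2 had 9.22 ± 0.682 and 14.4 ± 3.87 FPKM, COX8A 124 ± 12.1 and 192 ± 51.6, and COX5B 36.4 ± 6.76 and 59.8 ± 19.1 (SD, n = 3; adjusted p = 0.719 for each). NDUFB8 had 12.3 FPKM in MST3 replicate 1 and 2.87 to 5.02 FPKM in the other 5 libraries. Without MST3 replicate 1 the mean fell to 0.03 for ribosomal proteins and 0.05 for oxidative phosphorylation, and none of the 4 called lists passed.

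The 13 mitochondrially encoded mRNAs went mostly the other way, with 10 lower, a mean of -0.09 and a median of -0.28 (adjusted p = 0.0594 by camera). The list passed as lower, with the preset correlation, under equal library sums with and without STK24, median-of-ratios factors, no variance trend, the replicate block, voom and protein-coding genes alone. All of these used the preset 0.01, while the correlation estimated for this list in the main fit was 0.75. With that estimate camera gave an adjusted p = 0.843 in the main fit. MT-CYB had 2770 ± 514 and 1970 ± 109 FPKM (SD, n = 3), and MT-ND3 had 3510 FPKM in MST3 replicate 1 against 1060 to 1450 in the other 5 libraries. The vector libraries themselves differed in the median of this list, at 0.27, 0.07 and -0.35. The mean of the list was -0.35 without MST3 replicate 1 and -0.24 without vector replicate 3, which passed with the preset correlation, but 0.11 without MST3 replicate 3, 0.06 without vector replicate 1 and -0.01 without MST3 replicate 2, which did not. With all 6 libraries and an estimated correlation its adjusted p = 0.843. Mitochondrial dynamics and mitophagy genes split into 14 higher and 14 lower, with a mean of 0.01 and a median of 0.00 against a test direction of down (adjusted p = 0.944). HTRA2 had 5.31 and 6.32 FPKM and OPA1 11.7 and 10.2. Among NRF2 and antioxidant genes 12 were higher and 19 lower, with a mean of 0.04 and a test direction of up but a median of -0.03 (adjusted p = 0.86). SRXN1 had 1.9 ± 0.58 FPKM in vector and 4.56 ± 2.06 in MST3 libraries (SD, n = 3), a ratio of 2.4 with an adjusted p = 0.719. HMOX1 had 8.91 ± 1.53 and 10.7 ± 1.11 FPKM and GPX1 77.9 ± 6.08 and 105 ± 27.5 (SD, n = 3; adjusted p = 0.719 for each).

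**Figure D3:**
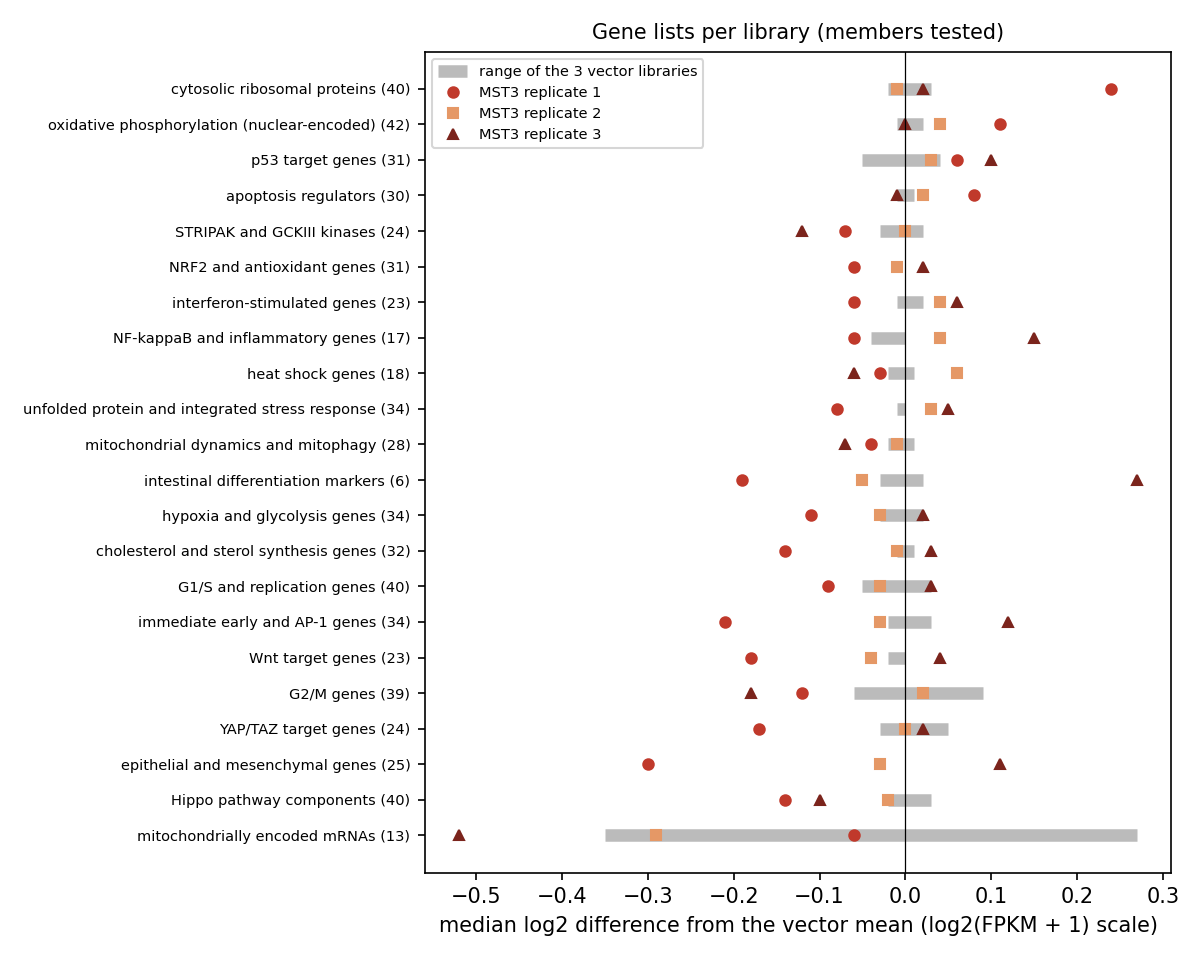
Median log2 difference from the vector mean for each of the 22 tested lists, with a grey bar for the range of the 3 vector libraries and a symbol for each MST3 replicate. Vector libraries are compared with a mean that includes themselves, which narrows their range, and for ribosomal proteins MST3 replicate 1 lies at 0.24 while replicates 2 and 3 lie at -0.01 and 0.02.

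G2/M mRNAs were lower for 34 of 39 genes, with a mean log2 difference of -0.07 and a median of -0.08. Camera gave an adjusted p = 0.038 with the preset correlation, and adjusted p = 0.843 with an estimated correlation. The median was -0.12, 0.02 and -0.18 in MST3 replicates 1 to 3, against -0.06, 0.09 and -0.03 in the vector libraries. TPX2 had 88.8 ± 5.84 and 77.4 ± 9.26 FPKM, MKI67 74.5 ± 4.07 and 64.8 ± 11.5 (SD, n = 3), and ANLN and BUB1 lay the same way. The mean moved to -0.03 without vector replicate 2 or MST3 replicate 3, and to -0.05 without MST3 replicate 1, and the list passed in none of these. G1/S and replication genes had 16 higher and 24 lower (mean -0.03, adjusted p = 0.516), with RRM2 at 75.3 and 59.4 FPKM and TYMS at 20.5 and 23.7. Among p53 target genes 19 of 31 were higher, with a mean of 0.08 and a median of 0.07 (adjusted p = 0.0772), and the list passed, with the preset correlation, by voom, with the replicate block and after removal of length and GC trends. With an estimated correlation its adjusted p = 0.843. FDXR had 20.6 ± 0.841 and 26 ± 4.04 FPKM, PHLDA3 6.34 ± 1.5 and 9.59 ± 2.66, and BAX 15.5 ± 2.22 and 19.5 ± 3.16 (SD, n = 3; adjusted p = 0.719 for each). Apoptosis regulators had 16 higher and 14 lower (mean 0.07, adjusted p = 0.342). BAD on that list had 6.41 ± 0.847 and 12.3 ± 4.79 FPKM (SD, n = 3; adjusted p = 0.719). Its groups overlapped, with 7.18 FPKM in MST3 replicate 2 and 7.26 in vector replicate 1. Wnt target genes had 9 higher and 14 lower (mean -0.04, adjusted p = 0.516), with BMP4 at 52.1 and 65.2 FPKM and DKK1 at 139 and 119.

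Stress, signalling and metabolic lists did not pass the test. Unfolded protein and integrated stress response genes had 16 higher and 18 lower, with a mean of 0.01 and a median of -0.00 (adjusted p = 0.987), and MANF had 19.3 and 25.3 FPKM while EDEM1 had 10.4 and 8.58. Heat shock genes had 10 higher and 8 lower (mean 0.02, adjusted p = 0.595), with HSPA1B at 13.1 and 15.9 FPKM. Immediate early and AP-1 genes had 12 higher and 22 lower (mean -0.04, adjusted p = 0.516), with JUNB at 105 and 139 FPKM and EGR1 at 259 and 218. Their mean was 0.04 without MST3 replicate 1, and -0.11 without MST3 replicate 3, where the list passed with the preset correlation (adjusted p = 0.00387) but with all 6 libraries and an estimated correlation had an adjusted p = 0.843. Interferon-stimulated genes had 13 higher and 10 lower (mean 0.03, adjusted p = 0.516), and ISG15 had 104 ± 4.39 and 126 ± 15.2 FPKM (SD, n = 3). NF-kappaB and inflammatory genes had 9 higher and 8 lower (mean 0.03, adjusted p = 0.516), with IER3 at 922 and 773 FPKM. Cholesterol synthesis genes had 11 higher and 21 lower (mean -0.02, adjusted p = 0.516). PMVK had 7.35 ± 0.465 and 11.7 ± 2.83 FPKM and IDI1 22.2 ± 0.678 and 18.1 ± 1.77 (SD, n = 3; adjusted p = 0.719 for each). Hypoxia and glycolysis genes had 12 higher and 22 lower (mean -0.01, adjusted p = 0.595), with KDM3A at 30.2 and 24.1 FPKM and CA9 at 6.28 and 7.24. Epithelial and mesenchymal genes had 8 higher and 17 lower, with a mean of -0.08 and a median of -0.12 (adjusted p = 0.0752), and their median was -0.30, -0.03 and 0.11 in MST3 replicates 1 to 3. Their mean was -0.00 without MST3 replicate 1, and -0.14 without MST3 replicate 3, where the list passed with the preset correlation (adjusted p = 0.00237), as it also did without a filter, with sample weights, with the replicate block, by voom and after removal of length and GC trends. With an estimated correlation its adjusted p = 0.843. FN1 had 4.98 and 4.17 FPKM and CDH1 36.4 and 30.4. Intestinal differentiation markers had 3 higher and 3 lower, with a mean of -0.01 and a test direction of down but a median of 0.01 (adjusted p = 0.987), and KRT19 had 939 and 976 FPKM. With an estimated correlation none of the 22 lists passed, the smallest p being 0.112 (adjusted p = 0.843), and fry called 0 lists, the smallest p being 0.118 (adjusted p = 0.69).

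The other 4 lists had fewer than 5 tested members. Of 27 replication-dependent histone genes 4 were tested, the highest being H1-2 at a mean of 15.7 FPKM. Of 18 fibroblast and stromal markers 3 were tested, with COL1A1 highest at 4.25 FPKM, and of 12 endothelial markers 1 was tested, ESAM at 4.38 FPKM. None of the 20 immune cell markers was tested, and FCER1G was the highest at 0.368 FPKM.

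Gene length separated the MST3 libraries from each other. Genes of 207 to 2967 bp had a median log2 difference from the vector mean of 0.10 in MST3 replicate 1, -0.00 in replicate 2 and 0.14 in replicate 3. Genes of 8243 to 44677 bp had -0.12, -0.00 and -0.10. The slopes per 10-fold length were -0.34, 0.00 and -0.25 in MST3 replicates 1 to 3, against -0.04, 0.05 and -0.02 in the vector libraries.

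**Figure D4:**
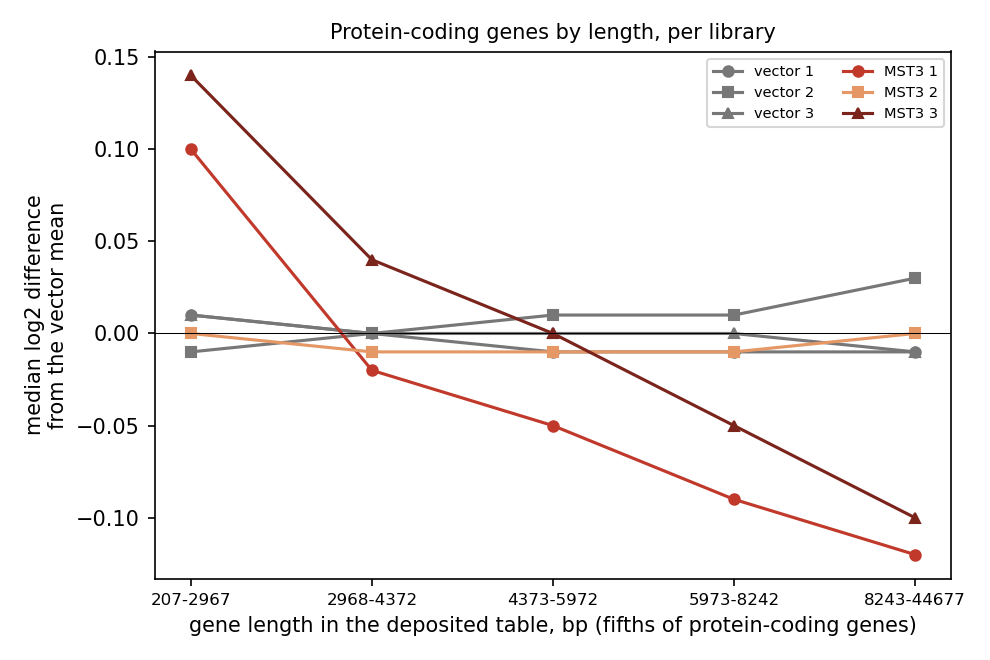
Median log2 difference from the vector mean in 5 bins of gene length (bp), with a line for each of the 6 libraries. MST3 replicates 1 and 3 run from 0.10 and 0.14 in the shortest bin to -0.12 and -0.10 in the longest, while replicate 2 stays at -0.00 in both.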

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

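The fit of voom to recovered reads, the removal of length and GC trends, the restriction to protein-coding genes and the fit without MST3 replicates 1 and 3 are tests chosen after the data were seen. Over the alternatives that refit the genes, the log2 difference of STK24 stayed between 1.91 and 2.06 with an adjusted p of 3.87e-07 to 0.0243, and the number of genes called stayed at 1, STK24 in each, including at 2-fold or more. The 4 called lists varied more. There were 2 with a filter at 0.1 FPKM (Hippo and G2/M), 2 with a filter at 5 FPKM (ribosomal and oxidative phosphorylation), 3 without a filter (Hippo, G2/M, and epithelial and mesenchymal genes), 0 after quantile normalization, 7 with the replicate number as a block and 7 by voom (the same 4, with mitochondrially encoded mRNAs, p53 targets, and epithelial and mesenchymal genes, in each) and 0 by fry, and the cause was not tested. There were also 4 with equal library sums and with sample weights, but not the same 4, since the G2/M list no longer passed and mitochondrially encoded mRNAs or epithelial and mesenchymal genes took its place. Camera with an estimated correlation differed by more than a wider error for lists whose genes vary together. For p53 targets the estimate was 0.02, near the preset 0.01, yet the p by camera went from 0.0245 to 0.112. The adjusted p = 0.843 was shared by lists with an unadjusted p of 0.112 to 0.728 in that test, so it does not rank them. With a correlation estimated per list there were 0 called lists. Without MST3 replicates 1 and 3 there were 0, with the lone MST3 library assumed to vary like the vector libraries, and the mean of G2/M genes there was 0.04, the opposite sign, with no call. Leaving out 1 library gave 1 to 6 lists, namely 2, 3 and 3 without vector replicates 1 to 3, and 1, 3 and 6 without MST3 replicates 1 to 3. Without vector replicate 1 the oxidative phosphorylation list (adjusted p = 0.0858) and the Hippo list (0.0815) no longer passed. Without vector replicate 2 the G2/M list (0.35) did not, nor without vector replicate 3 the ribosomal (0.0548) and oxidative phosphorylation lists (0.156). Without MST3 replicate 1 none of the 4 did, and the list called was that of mitochondrially encoded mRNAs (mean -0.35), which also passed without vector replicate 3 (-0.24) but had means of 0.11 without MST3 replicate 3 and 0.06 without vector replicate 1. Without MST3 replicate 2 the oxidative phosphorylation list (0.0578) did not pass, nor without MST3 replicate 3 the G2/M list (0.491), where YAP/TAZ targets (0.0288), immediate early genes (0.00387) and epithelial and mesenchymal genes (0.00237) passed. Of 2287 values of the 100 other genes chosen, 37 (in 21 genes) had another sign and 0 passed the threshold, and of 505 list values 30 (in 10 lists) had another direction, none called. YAP1 had a log2 difference of -0.78 to -0.57 and an adjusted p of 0.206 to 0.999. The replicate numbers were not used as pairs because the labels do not say that they mark a shared day or batch. Deviations from the group mean correlated at 0.02, 0.23 and 0.04 between vector and MST3 libraries of the same number. Between those of unlike number the correlations ran from -0.15 to 0.12. The median log2 difference of all genes lay within 0.03 of 0 under every alternative that refits the genes. At these depths 10 reads on a gene of 1 kb equal 0.569 to 0.627 FPKM, which limits the genes near the filter.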

Other observations

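The tests of a response shared by the MST3 libraries, of library depth, of GC content, of chance among many genes, of single libraries and of the gene counts under other splits were chosen after the results were seen, and the GC test, first set for both libraries together, was divided by library once its values were known.

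Short genes were higher and long genes lower in MST3 replicates 1 and 3, but not in replicate 2, whose slope of 0.00 lies among those of the vector libraries. Depth was argued against for replicate 3, which had 99.8% of the reads of replicate 2 and a slope of -0.25. Replicate 1 had the fewest reads, and thinning the others to its 15289213 reads moved their slopes by 0.00. The vector slopes stayed at -0.04, 0.05 and -0.02 and that of MST3 replicate 2 at 0.00, against -0.34 in replicate 1. Random thinning leaves the expected FPKM of each gene as it was. It could therefore hardly move a slope, and it decides nothing about depth in replicate 1. For that library its lower depth, whatever else came with it, and a response to MST3 cannot be told apart. GC content was argued against for replicate 1, which kept a share of 0.88 of its slope with GC in the model, but it may account for most of the trend in replicate 3, which kept 0.21 and had a GC slope of 0.22 per 10 points. A response shared by the MST3 libraries and a difference in preparation of single libraries cannot be told apart here, because the labels give no batches and the slope of replicate 2 counts against a shared response in 1 library alone. An exact permutation of the 6 slopes (p = 0.3) does not decide it, since it cannot go below 0.1.

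YAP1 mRNA was lower in the MST3 libraries. A trend with GC or with gene length in the deposited table was argued against as the whole cause, since the log2 difference after removing both was -0.60 (95% interval -0.87 to -0.33). A single library was argued against too, since the value nearest 0 with 1 library left out was -0.57. Chance among many genes and a fall in YAP1 mRNA after MST3 overexpression cannot be told apart, because the adjusted p = 0.719 over all genes while it was 0.00903 over the panel alone. That MST3 may lower YAP1 mRNA is therefore a hypothesis that these libraries leave open.

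Removing the trends left the ribosomal protein list at 0.13 (adjusted p = 0.00737 by camera with the preset correlation) and the oxidative phosphorylation list at 0.12 (adjusted p = 0.0128). Before the removal both had an adjusted p = 0.843 with an estimated correlation. Gene length was that of the deposited table, with medians of 3444 and 3151 bp for these lists, and not that of the transcripts expressed. The values therefore argue against trends with that length and with GC as the whole cause, and a trend with transcript length was not tested. The Hippo list went from -0.08 (SD over members 0.15) to -0.04 (0.12; adjusted p = 0.203) and the G2/M list from -0.07 (0.09) to -0.04 (0.09; adjusted p = 0.0732), so these calls ended because the means came nearer 0, and the trends and a response to MST3 cannot be told apart for them. With the preset correlation, used throughout here, p53 targets (0.06, adjusted p = 0.0398) and epithelial and mesenchymal genes (-0.10, adjusted p = 0.012) also passed, although before the removal both had an adjusted p = 0.843 with an estimated correlation and the epithelial list a mean of -0.00 without MST3 replicate 1. A single library may carry each of the 4 calls, since with 1 left out the mean nearest 0 was 0.03 for ribosomal proteins, 0.05 for oxidative phosphorylation and -0.03 for Hippo genes (each without MST3 replicate 1), and -0.03 for G2/M genes (without vector replicate 2 or MST3 replicate 3). A response to MST3 stays among the open explanations and was not tested apart from these.

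The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1 gene where the highest of the others called 0, at 2-fold or more 1 against 0, and 4 lists where the highest of the others called 8 and 5 of the 10 splits gave at least 4. At an unadjusted p under 0.05 the real split had 701 genes, and the split that set vector replicate 1 with MST3 replicates 1 and 3 had 1546, so the groups were not the division of the libraries with the most such genes.

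RN7SL2, a gene for the RNA of the signal recognition particle chosen after its values were seen, had 462 FPKM in MST3 replicate 1 and 23.2 and 23.5 in replicates 2 and 3, against 1.71, 5.06 and 7.64 in the vector libraries (log2 difference 3.64, adjusted p = 0.719). Its reads were 2213, 121 and 121 against 9, 26 and 40, and near-identical copies of this gene make the counting uncertain. An unannotated locus on a scaffold outside the assembled chromosomes that also carries ribosomal RNA genes, also chosen after its values were seen, had 120, 64 and 129 FPKM in the MST3 libraries and 40.8, 30.9 and 53 in the vector libraries, a ratio of 2.5 with a log2 difference of 1.27 (SE 0.30, adjusted p = 0.719). Genes with reads in 1 library alone numbered 1316 in MST3 replicate 1 and 663 to 754 in the other 5. The 725 pseudogenes among the tested genes took 0.877% of all reads in MST3 replicate 1, 0.675 and 0.7% in replicates 2 and 3, and 0.646 to 0.654% in the vector libraries.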
